A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

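Total RNA of 6 yeast cultures, 3 with WT Hsc82 and 3 with hsc82-W296A, was measured on Affymetrix arrays, 1 per culture. Per the labels, cultures grew in YPD, RNA was extracted with Trizol and labelled as biotinylated cRNA. The deposited values are on the log2 scale, as judged from their range, and were normalized across arrays by the authors. The submitters' processing notes name limma, with no role. The background correction, normalization and summarization of probes are not given in the sources used here. The mean over all probe sets lay between 8.91 and 8.92 on each array, but the spread differed.

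The array also carries probe sets for another species. Of 10928 probe sets, 7244 had 1 gene symbol in the platform annotation, 1 had several and 3683 were not listed. Gene names were brought up to date by gene ID through a gene table of assembly R64, which changed 12 symbols. This gave 5498 probe sets of 5449 S. cerevisiae genes, 1746 of the other species, 213 controls and 3470 unassigned. The 47 genes with several probe sets were represented by the one with the highest mean. No coordinates were used.

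Arrays have no depth, so signal over background limits what can be read. Background was set at the 95th percentile of the other-species means, 8.14, with 5172 S. cerevisiae probe sets above it and 326 at or below. The median of the other-species probe sets was 6.61 ± 0.092 (SD, n = 3) in WT Hsc82 and 6.42 ± 0.043 in hsc82-W296A, and that of the S. cerevisiae probe sets 10.99 ± 0.053 and 11.11 ± 0.035. An exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 against 3 arrays allow. The medians also ran in order within the groups. Other-species medians were 6.70, 6.63 and 6.52 in WT Hsc82 replicates 1 to 3 and 6.46, 6.43 and 6.38 in hsc82-W296A. Those of S. cerevisiae were 10.94, 10.99 and 11.04, then 11.07, 11.12 and 11.13. A drift over the arrays therefore cannot be told apart from the genotype in these medians. Correlations of arrays were 0.995 to 0.998 within groups and 0.917 to 0.941 between them, and no pair within a group held identical values.

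Each probe set was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, hsc82-W296A minus WT Hsc82 with no block, with Benjamini-Hochberg adjustment over 5498 probe sets and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 36 lists. The 36 lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Another 8 lists and 2 alternatives, background and middle matched and coding length trend removed, were chosen after seeing the data. The first rescales each array so that its medians over other-species and S. cerevisiae probe sets equal the means over the 6 arrays. The second subtracts a lowess trend on coding length.

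Genes were named by rule: HSC82 and HSP82, the 12 largest increases and 12 largest decreases past the threshold with no overlap of groups, and in each list up to 4 members with the smallest adjusted p. All members of the strain marker and mating-type lists could be given as values. Of list members, 10 ribosomal protein genes and some others had no probe set assigned and are not analysed here.

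Replicate numbers are shared between the groups. Deviations from the group means correlated at 0.405, 0.148 and 0.364 for the same-numbered pairs, each over 0.1, so the numbers were taken to pair the arrays, from the data and not from a label. Differently numbered arrays correlated from -0.387 to 0.139, with WT Hsc82 replicate 2 and hsc82-W296A replicate 3 at 0.139 and WT Hsc82 replicate 3 and hsc82-W296A replicate 2 at 0.107, so pair 2 stands out little. Array medians ran in replicate order in both groups, so a drift in that order cannot be told apart from pairing here. The other alternatives were quantile normalization, median centring, leaving out dim probe sets, probe sets with shared IDs or each array in turn, an intensity trend, a robust prior, array weights, no moderation and the use of all probe sets.

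The scripts were tested on simulated data. With 200 of 5498 probe sets changed, the fit called 21 of 50 at a log2 change of 0.25, 37 of 50 at 0.5, 48 of 50 at 1 and 50 of 50 at 2, and 4 unchanged ones. Camera called the 1 list raised by 0.5 and 0 others. This checks the scripts and does not measure how often camera makes false list calls on these arrays. On the arrays 3688 probe sets passed the threshold. Camera with the preset correlation called 7 to 18 lists when the arrays were split in ways other than by genotype. Tables and tests used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.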

Results

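Hsp90 is an abundant chaperone that helps many signalling proteins and other clients to fold. The series asked how gene expression differs in budding yeast when the only Hsp90 in the cell is a form of Hsc82 with a tryptophan replaced by alanine, hsc82-W296A. Strain JJ816 lacks both chromosomal Hsp90 genes, HSC82 and HSP82, and carries wild-type (WT) HSC82 or hsc82-W296A on a plasmid. RNA came from 3 cultures with WT Hsc82 and 3 with hsc82-W296A, grown in rich medium to exponential phase, and each was hybridised to 1 array. The labels name the samples as biological replicates, so p-values measure the spread between cultures. The number of arrays limits the precision. All changes are given as hsc82-W296A minus WT Hsc82 on the log2 scale, with the standard error of the limma fit and n = 3 arrays per group, and adjusted p-values are from that fit.

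The plasmid-borne gene was read first. HSC82 stood at 14.28 ± 0.035 (SD, n = 3) in WT Hsc82 and 14.54 ± 0.016 in hsc82-W296A, a change of 0.26 ± 0.041 (adjusted p = 0.00139). The highest value on an array was 14.79 to 14.93, so HSC82 lay near the top of the scale. Whether signal is compressed there was not tested. The probe set of HSP82, deleted per the labels, read above background on each array and stood at 10.03 ± 0.040 and 10.31 ± 0.055, a change of 0.29 ± 0.048 (adjusted p = 0.00179). HSC82 and HSP82 are near-identical, so HSC82 transcript can hybridise to the HSP82 probes, and these values check neither the deletion nor the substitution. The HSC82 change was -0.09 when the background and the middle of the arrays were matched, and the HSP82 change was 0.04 after quantile normalization, neither past the threshold. With the coding length trend removed they were 0.08 and 0.11, again not past it.

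Many genes differed between the genotypes, and the largest changes were increases. PIR3, a cell wall protein, rose by 4.67 ± 0.184 (adjusted p = 4.36e-06), and IDP2, a cytosolic isocitrate dehydrogenase, rose by 4.30 ± 0.088 (adjusted p = 6.26e-07). SHH3 rose by 4.27, TKL2, a transketolase, by 3.85, SPG4 by 3.82, YDL218W by 3.79 and SFC1, a mitochondrial succinate-fumarate carrier, by 3.71. MOH1 rose by 3.59, SPS100 by 3.58, ATG39, a receptor for autophagy of the nuclear envelope, by 3.49, GIP2 by 3.44 and PUT4, a proline permease, by 3.44. MOH1, SPS100, ATG39 and GIP2 lay below the background level of 8.14 in WT Hsc82, where array signal compresses differences, so the size of these rises is uncertain.

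Decreases reached less far on the measured scale. BSC1 changed by -2.81 (SE 0.070, adjusted p = 9.05e-07), YGR035C by -2.41 and YDR222W by -2.22. HXT1, a low-affinity glucose transporter, changed by -2.12 (SE 0.131, adjusted p = 2.33e-05). YMR230W-A changed by -1.97, ATF2, an alcohol acetyltransferase, by -1.94, PHO11, an acid phosphatase, by -1.93 and YOL014W by -1.78. PAD1 changed by -1.77, YHR214C-E by -1.68, CHA1, a serine and threonine deaminase, by -1.58 and PHM6 by -1.55. BSC1 and YHR214C-E lay below background in hsc82-W296A, at 7.60 and 6.78, so their falls are read against a floor and may be underestimates. The probes of PHO11 are marked by their ID as shared with other sequences.

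**Figure D1:**
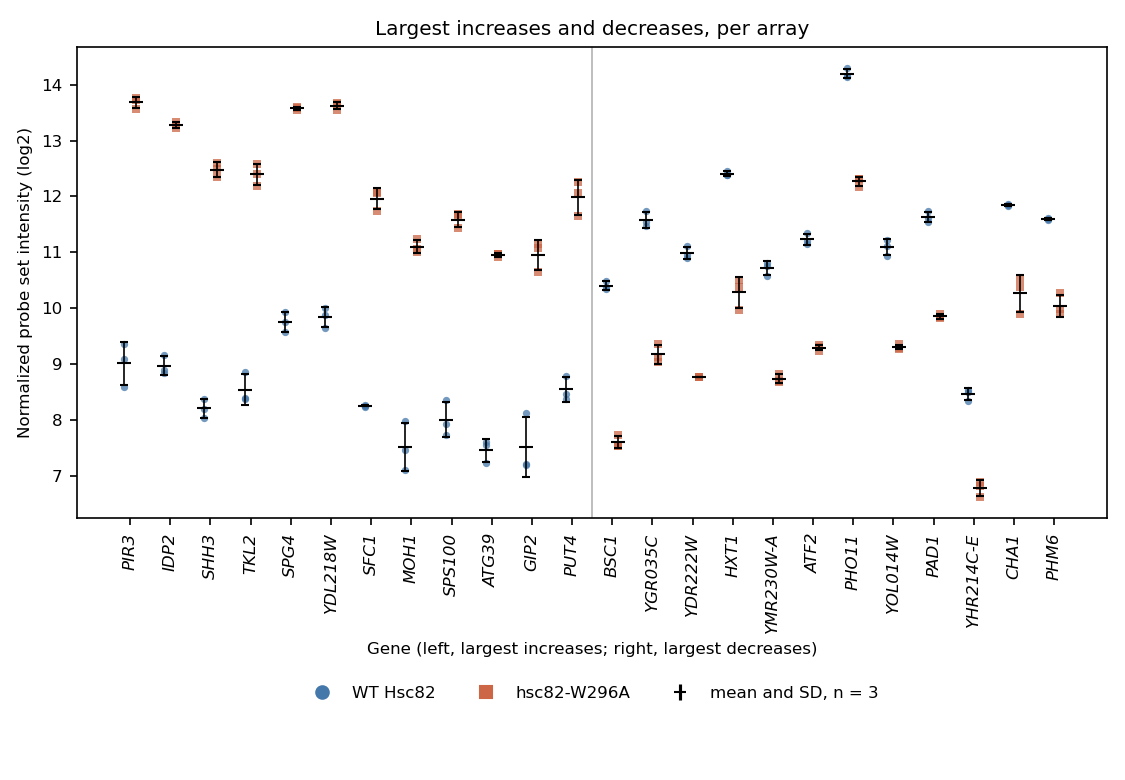
Normalized log2 intensity of the 12 genes with the largest increases and the 12 with the largest decreases; points are arrays, and black marks are the mean and SD of 3 arrays per genotype. PIR3 stands at 9.01 in WT Hsc82 and 13.68 in hsc82-W296A, and the arrays of the 2 genotypes do not overlap for any gene shown, which the choice of genes required.

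In total 3688 of 5498 S. cerevisiae probe sets passed the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), 2028 higher and 1660 lower in hsc82-W296A. By gene these were 3669 of 5449, or 67.3%, with 2019 higher and 1650 lower. At least 2-fold changes were fewer and mostly increases, with 487 probe sets higher and 48 lower. The decreases were 106 after quantile normalization, against 356 increases, 77 after median centring and 89 with background and middle matched. The groups did not overlap in 4039 probe sets, or 73.5%, where chance gives 10%. The split of higher and lower calls depends on the scaling: 55.0% of calls were higher as deposited, 39.0% after quantile normalization, 42.3% after median centring and 44.1% with background and middle matched. The median change of all probe sets was 0.04 as deposited, -0.09 after quantile normalization and -0.07 after median centring, and small changes are relative to these shifts.

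Genes of the general stress response that Msn2 and Msn4 control rose together. Of 35 members, 35 rose, 31 of them at least 2-fold, with a median change of 2.03, and 35 rose when adjusted over the list alone. ALD3, an aldehyde dehydrogenase, rose by 3.24 ± 0.062, MSC1 by 2.94, SPI1 by 2.49 and GPX1, a glutathione peroxidase, by 2.03. The list was called by camera with a preset correlation (adjusted p = 4.50e-14), but was not called at adjusted p = 0.520 with an estimated correlation, which was adjusted p = 0.0497 after median centring. In the osmotic response list of Hog1, 19 of 21 genes rose and 1 fell, the same counts as adjusted over the list alone, and PAI3 rose by 3.15, GRE1 by 3.08, CTT1, a catalase, by 2.60 and SIP18 by 2.30. This list had adjusted p = 2.71e-06 with the preset and adjusted p = 0.520 with an estimated correlation, and it shares 2 genes with the general stress list, CTT1 among them, and 2 with the oxidative stress list. Of 30 oxidative stress genes of Yap1 and Skn7, 22 rose and 4 fell, also when adjusted over the list alone. TSA2, a peroxiredoxin, rose by 2.51, PRX1 by 1.43, SRX1 by 1.32 and GTT1 by 1.25, with adjusted p = 0.00311 for the list and adjusted p = 0.542 with an estimated correlation.

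Genes for the use of non-fermentable carbon were also higher. In the tricarboxylic acid and glyoxylate cycle list, 22 of 23 genes rose and 1 fell, also when adjusted over the list alone, with a median of 0.90. ICL1 and MLS1, the glyoxylate cycle enzymes, rose by 2.31 and 2.13, and MDH2 rose by 1.97. The list had adjusted p = 4.47e-07 and adjusted p = 0.542 with an estimated correlation, or 0.0497 after median centring. Of 31 glucose-repressed and hexose transport genes, 22 rose and 6 fell, or 24 and 6 when adjusted over the list alone, with a median of 0.64. ADH2, the ethanol-oxidising alcohol dehydrogenase, rose by 3.37, HXT5 by 3.32 and PCK1, a gluconeogenic enzyme, by 2.72, whereas HXT1 of the same list fell. It had adjusted p = 0.00187 and adjusted p = 0.542 with an estimated correlation, and its median was 0.25 after quantile normalization. Of 39 respiratory chain and ATP synthase genes, 39 rose, also when adjusted over the list alone, with NDE2 at 2.84, SDH2 at 1.22 and SDH4 at 0.83. The median was 0.42 (adjusted p = 1.36e-09, and adjusted p = 0.542 with an estimated correlation), and it was 0.13 with background and middle matched, where 14 of the 39 rose.

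Cell wall genes of the Rlm1 pathway rose, 29 of 30 with 1 lower, also when adjusted over the list alone. Besides PIR3, BAG7 rose by 2.33, PST1 by 1.56 and CRG1 by 1.35, and the median was 0.76. BAG7 started from 7.72, below background, so the size of its rise is uncertain. The list had adjusted p = 2.20e-07 and adjusted p = 0.542 with an estimated correlation. Of 36 nitrogen catabolite repression genes, 26 rose and 2 fell, also when adjusted over the list alone, and 9 fell after quantile normalization. PRB1, a vacuolar protease, rose by 3.12, GDH2 by 1.89, PUT1 by 1.51 and AGP1 by 1.18, with adjusted p = 0.000600 and adjusted p = 0.542 with an estimated correlation. The median of 0.54 was 0.29 after quantile normalization.

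Increases were also found in sulfur genes, in genes of NAD and thiamine synthesis and in genes of the G2/M and M/G1 phases. Of 35 sulfur and methionine genes, 26 rose and 7 fell, also when adjusted over the list alone, with MET28, a transcription factor, at 1.68, JLP1 at 1.08, YCT1 at 1.04 and MHT1 at -0.79, and JLP1 and YCT1 were at 0.60 and 0.63 after quantile normalization. The list shares 3 genes with the oxidative stress list. It had adjusted p = 0.00641 and adjusted p = 0.542 with an estimated correlation. Of 17 genes of NAD and thiamine synthesis, 15 rose and 0 fell, also when adjusted over the list alone, with THI13, whose probes are shared with other genes, at 1.41, THI4 at 1.17 and THI20 at 1.12. The list had adjusted p = 0.000725 and adjusted p = 0.542 with an estimated correlation, and its median of 0.48 was 0.25 after quantile normalization. Of 35 genes of the G2/M and M/G1 phases, 27 rose and 0 fell, also when adjusted over the list alone, and 5 fell with background and middle matched, with ASH1 at 1.36, SIC1, an inhibitor of cyclin-dependent kinase, at 1.27 and PIR1 at 1.14. The list shares 3 genes with the cell wall list, PIR1 and PST1 among them, so these are not separate lines of evidence. The G2/M and M/G1 list had adjusted p = 0.000697 and adjusted p = 0.542 with an estimated correlation, and its median of 0.36 was 0.24 with background and middle matched and 0.21 with the coding length trend removed.

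Genes for making ribosomes were lower. Of 70 ribosome biogenesis genes, 57 fell and 1 rose, or 58 and 1 when adjusted over the list alone. DBP8, an RNA helicase, fell by 1.07, ENP1 by 0.83, NOP7 by 0.65 and TIF6 by 0.64. The median was -0.45 (adjusted p = 4.50e-14, and adjusted p = 0.114 with an estimated correlation), and -0.70 with background and middle matched. Of 127 cytosolic ribosomal protein genes, 47 fell and 0 rose, and 38 fell when adjusted over the list alone, but 111 fell after median centring and 126 with background and middle matched. As deposited 80 of the 127 did not pass, and of all 5449 genes 1650 were called lower. RPL4B fell by 0.56, RPS9A and RPL22B by 0.54 and RPL13A by 0.36, and RPL22B and RPL13A changed by -0.82 and -0.68 with background and middle matched, but paralogs in this family can share probes. The median of -0.08 (adjusted p = 3.70e-06, and adjusted p = 0.542 with an estimated correlation) was -0.20 after median centring and -0.42 with background and middle matched, and with the coding length trend removed it was -0.03 and the call ended (adjusted p = 0.0517). Of 29 ergosterol genes, 14 fell and 4 rose, also when adjusted over the list alone, or 22 and 1 after median centring, with MVD1 at -0.72, ERG26 at -0.64 and ERG3 at -0.46. This list had adjusted p = 0.00873 and adjusted p = 0.542 with an estimated correlation, and its median of -0.19 was -0.31 after median centring and -0.41 with background and middle matched.

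Chaperone genes went in different directions. Of 14 Hsp90 co-chaperones, 6 fell and 0 rose, also when adjusted over the list alone, but 12 fell after quantile normalization or median centring and 13 with background and middle matched. As deposited 8 of the 14 did not pass. CNS1 fell by 0.96 ± 0.058, PPT1, a protein phosphatase that binds Hsp90, by 0.88 ± 0.044, CPR7 by 0.35 and HCH1, an activator of the Hsp90 ATPase, by 0.34. The median of -0.14 (adjusted p = 0.0156, and adjusted p = 0.542 with an estimated correlation) was -0.26 after median centring and -0.38 with background and middle matched. In the chaperonin TRiC and prefoldin list, 12 of 15 genes fell and 0 rose, also when adjusted over the list alone, and the prefoldin genes GIM4, GIM5 and GIM3 fell by 0.64, 0.48 and 0.35. It had adjusted p = 0.000725 and adjusted p = 0.542 with an estimated correlation, and its median of -0.25 was -0.47 with background and middle matched. Of 23 targets of the heat shock factor Hsf1, 13 rose and 4 fell, also when adjusted over the list alone, but 8 rose and 8 fell after median centring, and 8 rose and 10 fell with background and middle matched. SSA3 and SSA4, inducible Hsp70 genes, rose by 2.89 and 1.74, HSP78 by 0.91 and HSP104, a disaggregase, by 0.89. The Hsf1 and co-chaperone lists share members, HCH1, which fell, among them, so they are not separate groups of genes. The Hsf1 list was not called by camera (adjusted p = 0.224) but was by fry (adjusted p = 0.00321). Its median was 0.20, or -0.05 with background and middle matched.

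**Figure D2:**
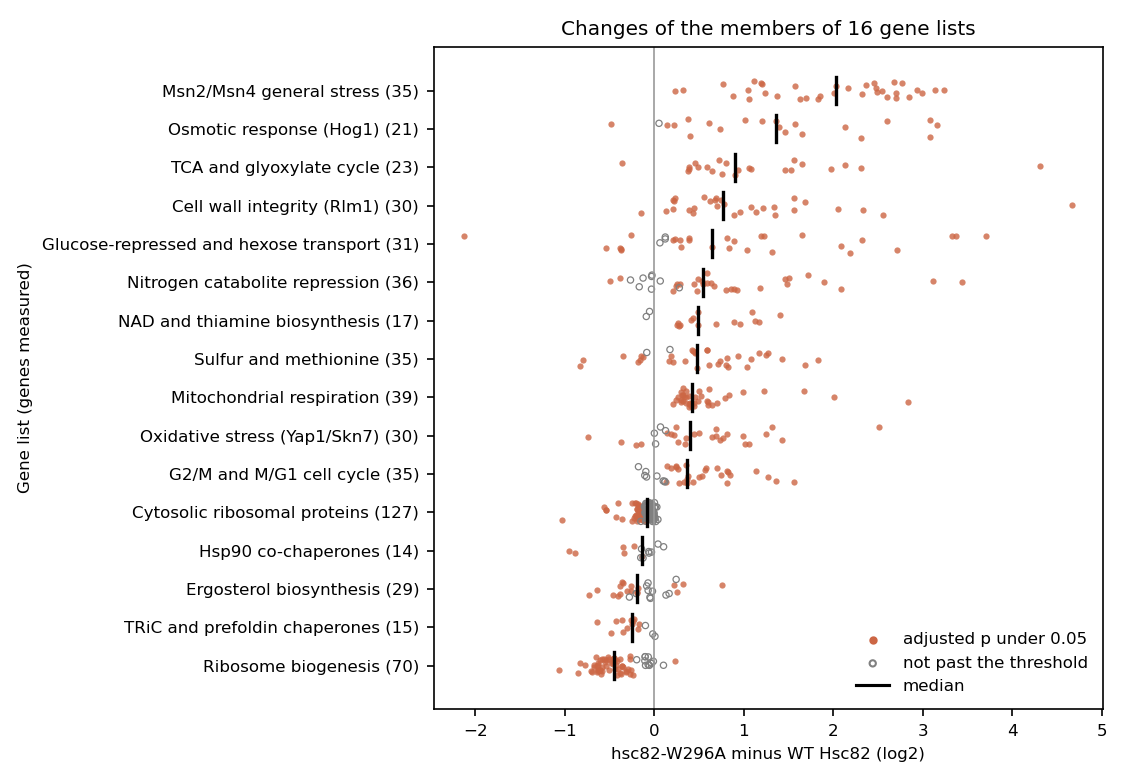
Change of each member of the 16 gene lists called by camera with the preset correlation, on the log2 scale; filled points passed the threshold, open points did not, and black lines are medians. The median runs from 2.03 for the general stress list to -0.45 for ribosome biogenesis.

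Other lists were not called by camera as deposited, though members of each passed the threshold, as did 67.3% of all genes. Fry called 14 of the lists that camera with the preset correlation did not, phosphate (fry adjusted p = 0.00130) and Gcn4 (fry adjusted p = 0.0207) among them. The tests thus disagree on these lists, and the adjusted p-values given next are from camera. The counts higher and lower were 14 and 6 of 29 for pheromone response, 12 and 7 of 29 for iron and 21 and 11 of 46 for Gcn4. For purines they were 13 and 4 of 19, and for G1/S 13 and 11 of 34. In the pheromone response list (adjusted p = 0.509) PRM5 rose by 1.34 and SST2, a negative regulator of the pathway, fell by 1.30. In the phosphate list (adjusted p = 0.214) 7 of 19 genes rose, 2 at least 2-fold, and 10 fell, 4 at least 2-fold. There PIC2 rose by 1.67, while PHO11 changed by -1.93, PHM6 by -1.55 and VTC3, of the polyphosphate polymerase complex, by -0.83. In the iron list (adjusted p = 0.646) HMX1, a heme oxygenase, rose by 1.37 and FRE4 fell by 0.80. In the amino acid list of Gcn4 (adjusted p = 0.396) SNO1 rose by 2.54 and SNZ1 by 2.10. In the list of heme-dependent genes (adjusted p = 0.527) CYB2 rose by 2.19, and in the glycolysis list (adjusted p = 0.523) HXK2, a hexokinase, fell by 0.82. Lists of the proteasome, the unfolded protein response, drug resistance, histones, G1/S, phospholipids, zinc, purines and box C/D particles had adjusted p-values of 0.787, 0.214, 0.224, 0.214, 0.787, 0.224, 0.559, 0.151 and 0.131. The proteasome list was called, lower, with background and middle matched (adjusted p = 0.0307, and adjusted p = 0.802 with an estimated correlation), and the purine list, higher, after quantile normalization (adjusted p = 0.0298, and adjusted p = 0.462 with an estimated correlation). For G1/S the median was 0.0076 and the mean 0.07 while camera pointed down, and for zinc the mean was 0.20 and the median -0.08.

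Markers of the strain and of cell type were read as values. HIS3 rose by 1.02 ± 0.049 (adjusted p = 8.67e-06) and LEU2 by 0.45 ± 0.051, and URA3 stood at -0.17 ± 0.093 without passing the threshold. With background and middle matched the LEU2 change was 0.16 and no longer passed (adjusted p = 0.128), and that of URA3 was -0.38 and passed (adjusted p = 0.00581). Among genes of MATa cells, AGA2 rose by 0.98, and STE2 and BAR1 changed by -0.21 and -0.23, or -0.49 and -0.43 with background and middle matched. Among genes of MATalpha cells, MF(ALPHA)1 rose by 1.86 from 7.60 and STE3 by 1.15 from 7.90, both from below background, and the STE3 change was 0.68 after quantile normalization. The lists of strain markers, MATa, MATalpha and sporulation genes were not called by camera (adjusted p = 0.509, 0.774, 0.146 and 0.0607). Fry called these lists except MATa (fry adjusted p = 0.00179, 0.205, 0.000789 and 0.000296). IME2 of the sporulation list rose by 2.15 from 7.90, also below background. Camera called the MATalpha list with background and middle matched (adjusted p = 0.0307, and adjusted p = 0.527 with an estimated correlation). The sporulation list was called by camera there (adjusted p = 0.0117), after median centring (adjusted p = 0.0224) and without WT Hsc82 replicate 1 (adjusted p = 0.0280), with adjusted p = 0.224, 0.235 and 0.498 with an estimated correlation.

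Camera with the preset correlation called 16 of 36 lists, 11 higher and 5 lower, and with an estimated correlation it called 0 as deposited and 2 after median centring. It also called between 7 and 18 lists in the 9 other ways to split the 6 arrays into 3 and 3, so a call of this test alone does not mark the genotype. Those splits are not free of the genotype, since each sets 2 arrays of one genotype and 1 of the other against the reverse.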

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

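All tests of explanations here and under the other observations were chosen after the results were seen. Among the 3470 probe sets with no gene assigned, 287 lay above the background level on all 6 arrays, a signal outside the comparisons of named genes. Of the 287, 229 passed the threshold when all probe sets on the array were fitted, 99 higher and 130 lower in hsc82-W296A, with 35 at least 2-fold higher and 2 at least 2-fold lower. In that fit 5730 of all 10928 probe sets passed. No biological explanation of this signal was tested.

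The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype split called 3688 probe sets, 1 of the 10 splits gave as many, and the highest of the others was 0 by limma, with up to 158 at an unadjusted p under 0.05. The 3 other splits that part each same-numbered pair also called 0. For gene lists called by camera with the preset correlation, 3 of the 10 splits gave as many as the 16 of the genotype split, the genotype split included, and the highest other was 18. The 3 other splits that part each same-numbered pair called 14, 15 and 12 lists. With an estimated correlation the count was 0 in each of the 10.

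Increases of at least 2-fold outnumbered decreases, 487 against 48. Normalization by the authors over the whole array could account for this, since the share of other-species signal differed, but increases were still 77.1% of such changes under the least favourable of 3 other scalings. Dim probe sets could too, but without them increases were 90.6%. These values argue against either as the whole cause, though the scaling changes the size of the excess. A difference between the genotypes stays open and was not tested apart from them.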

How the results depend on the processing

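Of 164 named genes, 146 kept their direction and side of the threshold in each setting, and 18 did not. Of 16 called lists, 15 were called by camera with the preset correlation in each of 18 settings. The alternatives with background and middle matched and with the coding length trend removed were chosen after seeing the data. Where no reason is given, the cause was not tested. The pseudocount alternative was not run, since the values are log2. Signal over background limits the changes of dim genes.

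The count of 3688 was 5730 with all probe sets on the array, 3637 of them lower, since other-species and unassigned probe sets were then tested too, and 535 with at least 2-fold change required. Leaving out each array gave 3189 to 3713. Decreases of at least 2-fold, 48 as deposited, were 106 after quantile normalization, 77 after median centring and 89 with background and middle matched. With the replicate number as a block for the pairing, 4007 probe sets and 16 lists were called, and it changed no call of a named gene or list. List calls numbered 0 with an estimated correlation and 30 with fry, and after median centring 2 lists, general stress and the tricarboxylic acid cycle, were called with an estimated correlation (adjusted p = 0.0497 for both).

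HSC82 changed by -0.088 with background and middle matched and 0.084 with the length trend removed. HSP82 changed by 0.043 after quantile normalization and 0.11 with the length trend removed.

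With background and middle matched, medians of lists that camera did not call as deposited turned to -0.047 for Hsf1 targets, -0.074 for heme-dependent genes, -0.056 for Gcn4, -0.23 for the proteasome, -0.27 for glycolysis, -0.096 for G1/S and -0.18 for mitochondrial ribosomal proteins. After median centring they were -0.00084 for heme-dependent genes, -0.015 for iron, -0.032 for Gcn4, -0.085 for the proteasome, -0.078 for glycolysis, -0.11 for G1/S and -0.093 for mitochondrial ribosomal proteins. After quantile normalization they were -0.046 for pheromone, -0.032 for iron, -0.028 for the proteasome, -0.031 for drug resistance, -0.21 for G1/S and -0.037 for mitochondrial ribosomal proteins. With the length trend removed they were -0.0053 for iron and -0.11 for G1/S, and with array weights -0.028 for G1/S. Lists gained as calls of camera with the preset correlation were the proteasome (lower), MATalpha and sporulation and, among the added lists, mitochondrial ribosomal proteins (lower, adjusted p = 0.0410) with background and middle matched, purines after quantile normalization, and sporulation after median centring and without WT Hsc82 replicate 1. Leaving out each array gave -0.00347 to 0.18 for iron, -0.050 to 0.052 for G1/S and -0.0109 to 0.043 for mitochondrial ribosomal proteins.

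With background and middle matched, MET17 changed by -0.13, LYS2 by 0.0067, MFA2 by -0.28 and MF(ALPHA)2 by 0.13, and MFA2 by -0.073 after median centring. With background and middle matched, HCH1 changed by -0.62, GIM3 by -0.59 and ERG3 by -0.72. Leaving out each array gave -0.042 to 0.023 for MF(ALPHA)2.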

Other observations

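Further gene groups were put together after the values were seen and adjusted among 8 lists, of which camera with the preset correlation called 7. Since the values could guide the choice of lists, the p-values of these 8 lists are descriptive and do not count as tests. Of 12 glycogen metabolism genes, 12 rose, with a median of 1.59 (limma camera, adjusted p = 1.32e-05, and adjusted p = 0.181 with an estimated correlation), and GLC3, GSY2, GDB1 and GPH1 belong to the general stress list too. Of 34 autophagy genes, 27 rose and 3 fell, with a median of 0.63, or 0.39 after quantile normalization (adjusted p = 1.32e-05, and adjusted p = 0.298 with an estimated correlation). Of 15 genes of peroxisomal fatty acid oxidation, 12 rose and 2 fell, with a median of 0.94, or 0.61 after quantile normalization, and of 11 vacuolar hydrolases 9 rose and 0 fell (adjusted p = 0.00287 and 0.00124, both adjusted p = 0.298 with an estimated correlation).

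Genes that serve translation outside the ribosome were lower. Of 32 tRNA modification genes, 28 fell and 1 rose, with a median of -0.50 (adjusted p = 2.71e-08, and adjusted p = 0.0705 with an estimated correlation). Of 13 RNA polymerase III genes, 9 fell and 0 rose, with a median of -0.44, or -0.71 with background and middle matched (adjusted p = 0.00124, and adjusted p = 0.0982 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, 15 fell and 0 rose, with a median of -0.24, or -0.53 with background and middle matched (adjusted p = 6.08e-05, and adjusted p = 0.298 with an estimated correlation). Of 66 mitochondrial ribosomal protein genes, 19 rose and 5 fell, and the list was not called (adjusted p = 0.664), but with background and middle matched it was called lower (median -0.18, adjusted p = 0.0410, and adjusted p = 0.712 with an estimated correlation). Chromosome medians ran from -0.03 for chromosome XIV to 0.18 for chromosome I.

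The tests of explanations below were chosen after the results were seen. Longer genes stood higher in hsc82-W296A, with a median change of 0.18 in the 1818 genes with the longest coding length and -0.06 in the 1821 with the shortest, and a Spearman rho of 0.194 across 5449 genes, which are not independent replicates, but of only 0.0735 among 2712 genes over log2 11 in WT Hsc82. Less loss of RNA 5′ ends in hsc82-W296A could give this. The 5′ minus 3′ signal of 8 control transcripts differed by -0.00068 between the genotypes, within its SD of 0.047 between arrays. It was higher in hsc82-W296A for 2 of them, TDH1 by 0.33 and RIP1 by 0.15, and lower for the others. Without TDH1, which like RIP1 itself changed, the difference was -0.047, within its SD of 0.049. Differences within the spread between arrays cannot decide this. The gap between long and short genes was higher in hsc82-W296A by 0.203, 0.265 and 0.215 in the same-numbered pairs, a range of 0.272 of their mean, whereas arrays within a group ranged over 0.782 of the group difference. A technical trend of the arrays stays open, since the pairing was inferred from the data and a trend common to the arrays of a genotype cannot be told apart from the genotype, which was not tested apart from it.

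General stress and glucose-repressed genes were higher in hsc82-W296A. A difference in scale between arrays could raise them, since the middle of the S. cerevisiae probe sets was higher in hsc82-W296A, though the lower background there would lower dim genes, and the lowest median over 3 other scalings was 1.90 for the general stress list. With the length trend removed the medians were 2.08 and, for the glucose-repressed list, 0.53, so scale does not account for the whole of the stress rise, nor length for that of either list. The glucose-repressed median, 0.64 as deposited, was 0.25 after quantile normalization, 0.53 after median centring and 0.69 with background and middle matched. Camera with the preset correlation called that list under each scaling. The lower value after quantile normalization leaves open how much of its rise scale accounts for. Cultures nearer to glucose exhaustion could raise both lists, and SUC2, HXT2 and HXT4, genes induced by low glucose and chosen after their values were seen, had a median change of 0.0623, with values of 0.06, 0.12 and -0.37. This does not decide it, and a rise of HXT7, also induced by low glucose, by 1.04 and the change of HXT1 by -2.12 go with exhaustion. SUC2 and these HXT genes are members of the glucose-repressed list, so they are not independent of the rise in question. In that list 22 of 31 genes rose and 6 fell, with FBP1 at 2.18 and JEN1 at 2.33. A difference in culture state and an effect of hsc82-W296A itself both stay open.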
